A study of Mus musculus with 8 samples.

How the data were processed

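RNA-seq was done on microglia, the resident macrophages of the brain, isolated from brains of 6-month-old C57BL/6 mice. Per the labels, the 8 libraries fall into 4 groups of 2: wild type (WT), Calhm2 conditional knockout (cKO), wild type with Alzheimer's disease (WT/AD) and Calhm2 conditional knockout with Alzheimer's disease (cKO/AD). The labels do not name the mouse model of Alzheimer's disease or the Cre driver, and the series design writes one group in a form that differs from the sample labels; the sample labels were used. Group and replicate number were taken from the source name of each sample. Nothing in the labels says that the 2 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

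Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit. The authors deposited 1 table of whole-number read counts per gene for 55421 genes and 8 libraries, with Ensembl gene identifiers and gene symbols; the deposited counts are not normalised. The genome build mm9 is named per the submitters' processing notes. The aligner, the counting tool and the strand setting are not given in the sources used here. Of the identifiers, 54587 matched the GENCODE M21 annotation with their version and 55154 without it. This annotation is of a later build than mm9, so no coordinates are printed, and the annotation was used only for transcript GC content and length. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and counts of near-identical genes are uncertain. No column was without a sample (0 unused).

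Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group, which left 22089 tested genes, and libraries were scaled with TMM factors, which ranged from 0.873 to 1.11. A group means model was fitted to all 8 libraries with the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided). The groups therefore share 1 estimate of the spread with 4 residual degrees of freedom. The Benjamini-Hochberg adjustment ran over all tested genes within a comparison and the threshold was an adjusted p of 0.05. The 5 comparisons were WT/AD against WT, cKO against WT, cKO/AD against WT/AD, cKO/AD against cKO, and the interaction, which is the cKO/AD minus WT/AD difference minus the cKO minus WT difference. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Unless another tool is named, every adjusted p of a gene is from this edgeR test. Levels are CPM over the TMM-scaled library size, as mean ± SD over n = 2 libraries. Library totals ranged from 18218165 to 25774587 counts. A gene with 0 counts in a group was bounded by 3 counts over the group; a ratio with 1 to 3 counts in a group has an exact 95% interval. Intervals and floors cover counting error only.

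Before the data were examined, 28 gene lists and the rule for named genes were fixed. The rule takes Calhm2 in every comparison. Among genes past the threshold it takes those whose groups do not overlap in CPM, with a mean of at least 5 CPM in the higher group and a symbol that is not a predicted-gene, clone or microRNA name. Of these it takes the 10 largest rises and the 10 largest falls. It then takes up to 4 members past the threshold from each list, smallest adjusted p first. With fewer than 10 genes past the threshold, all are named, followed by the 10 with the smallest raw p. Apoe, Trem2, Cst7, Clec7a, Itgax, P2ry12, Tmem119, Il1b, Tnf, Nlrp3, H2-Aa and Ifit3 are always given. Not every gene the rule takes is printed, and 1 gene result is not reported here. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Of 557 listed genes found in the table, 537 were tested; sex-linked genes were listed only as a check of the samples.

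The alternatives were DESeq2 1.42.0 (Wald test, and its size factors in edgeR), limma-voom, library size without TMM, no filter, a stricter filter, only the 2 groups compared, a block for the replicate number, a 2-fold minimum and leaving out each library. For lists, camera with an estimated correlation was run, and fry, which does not set a list against the other genes. Chosen after seeing the data were a correction for GC content, that correction with the replicate block, and voom with a weight per group. For the GC correction, a loess curve (span 0.4) of each library's deviation from the mean log2 CPM was fitted on transcript GC content over genes above a mean log2 CPM of 2 and added as an offset; 99.87% of tested genes had a GC value.

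The scripts were tested on simulated data for WT/AD against WT, with 200 genes changed and the pooled spread of the real libraries. Of 20974 genes run, edgeR called 3 of 66 genes changed 2-fold (log2 of 1), 26 of 67 with a log2 change of 2 and 46 of 67 with a log2 change of 3, with 4 false calls. On the same data DESeq2 made 46 false calls and limma-voom 1. A simulated list of 25 genes shifted by a log2 of 1 was recovered by camera at an adjusted p of 5.86e-05, and 0 of 27 lists without a shift passed.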

Results

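The transcriptome of isolated microglia was measured by RNA-seq in 4 groups of 6-month-old mice with 2 libraries each: WT, Calhm2 cKO, WT/AD and cKO/AD. Calhm2 encodes a membrane channel protein of the calcium homeostasis modulator family. The libraries held 21167329 and 20285194 counts in WT, 18218165 and 20951295 in cKO, 25436631 and 25774587 in WT/AD, and 20188506 and 22416026 in cKO/AD. The 2 libraries of a group correlated across tested genes at r = 0.93 in WT, 0.939 in cKO and 0.945 in WT/AD, but at 0.843 in cKO/AD (log2 CPM). The SD of the replicate difference was 2.07 on the log2 scale in cKO/AD and between 1.03 and 1.17 in the other groups. All replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of at least 19.4. The first cKO/AD library had the fewest genes with a count, 18693, against 22088 in the second cKO/AD library and between 24342 and 25988 elsewhere.

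Calhm2 (ENSMUSG00000033033.10), the targeted gene, was lower in both knockout groups than in the matched controls. It stood at 11.2 ± 1.25 CPM in WT and 4.73 ± 0.043 CPM in cKO, and at 15.1 ± 1.86 CPM in WT/AD and 2.03 ± 0.662 CPM in cKO/AD (mean ± SD, n = 2). The raw counts were 216 and 239 in WT, 96 and 107 in cKO, 412 and 347 in WT/AD, and 44 and 35 in cKO/AD, so both knockout libraries lay below both control libraries in each pair. In AD mice Calhm2 fell by 2.89 on the log2 scale (SE 0.495, edgeR adjusted p = 0.01). Without AD the log2 difference was -1.24 (SE 0.466), which did not pass the threshold (edgeR adjusted p = 0.673). A conditional deletion can leave reads from exons outside the deleted part, and from cells in which no recombination took place.

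**Figure D1:**
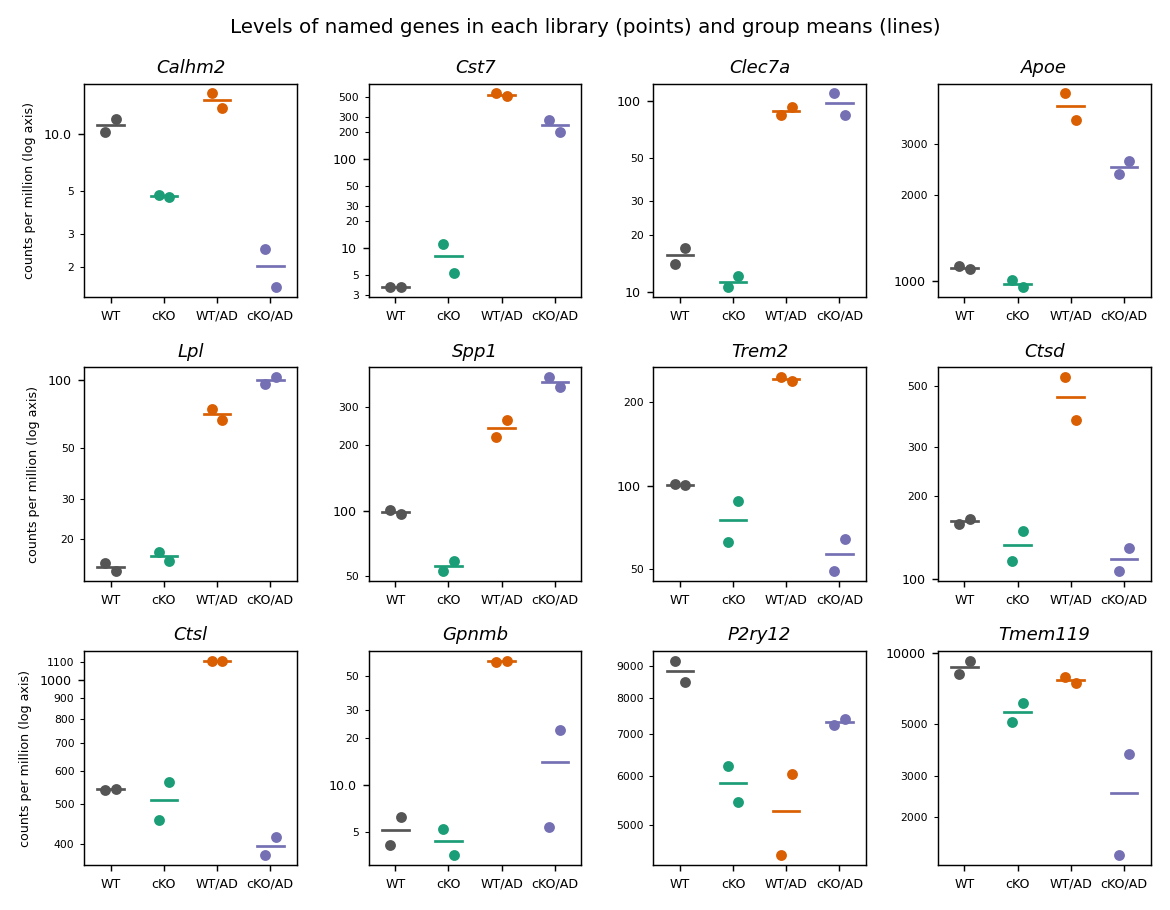
CPM (log axes) of Calhm2 and 11 microglial genes in each of the 8 libraries (points, 2 per group) with the group means (lines). Calhm2 is lowest in both cKO groups, while Cst7 rises from 3.64 CPM in WT to 532.1 CPM in WT/AD and 239.9 CPM in cKO/AD.

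The comparison of WT/AD with WT asked what changes in microglia of AD mice with Calhm2 intact. Genes of the disease-associated microglia (DAM) programme were higher in WT/AD. Cst7, a cysteine protease inhibitor, rose from 3.64 ± 0.0461 to 532.1 ± 25.9 CPM (log2 fold change 7.19, SE 0.429, adjusted p = 0.00203). Clec7a, a pattern recognition receptor, rose from 15.6 ± 2.13 to 88.8 ± 5.89 CPM, Lpl, the lipoprotein lipase gene, from 15 ± 0.905 to 70.4 ± 5.06 CPM, and Apoe, which encodes a lipid carrier, from 1109 ± 22.3 to 4089 ± 629 CPM (log2 fold changes 2.51, 2.23 and 1.88; adjusted p between 0.0284 and 0.0353). Of the 26 DAM genes, 26 had a positive fold change; 4 rose over all genes tested and 22 adjusted over the list alone. The list median was a log2 fold change of 1.36 (camera adjusted p = 1.72e-22, and adjusted p = 0.00981 with an estimated correlation).

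Outside the DAM list, Ctse, which encodes an aspartic protease, rose from 5 ± 0.759 to 45.8 ± 2.18 CPM, the chemokine gene Ccl3 from 11.8 ± 0.623 to 99.96 ± 2.5 CPM, and Ptgds, which encodes a prostaglandin D synthase, from 144.2 ± 1.09 to 806.1 ± 195 CPM. In all, 7 genes rose and 3 fell (edgeR). The 3 that fell, Gm10800, Gm10801 and Gm21738, are predicted genes whose counts are uncertain where reads are shared between copies. Gm10800 was at 750.2 ± 136 CPM in WT and 0.436 ± 0.111 CPM in WT/AD. Gm21738 had 1214 counts in WT and 3 in WT/AD, and Gm10801 had 2153 counts in WT and 1 in WT/AD. Trem2 (101 ± 0.339 against 242.7 ± 4.69 CPM, adjusted p = 0.198) and Itgax (3.6 ± 1.25 against 28.4 ± 5.6 CPM, adjusted p = 0.127) had log2 fold changes of 1.26 and 2.98. P2ry12 was at 8828 ± 476 and 5263 ± 1110 CPM and Tmem119 at 8707 ± 810 and 7699 ± 359 CPM in WT and WT/AD (adjusted p = 0.367 and 0.98).

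Lists of other cell types also differed between WT/AD and WT. Endothelial markers were lower, with a median log2 fold change of -1.19 over 16 genes and 8 that fell adjusted over the list alone, among them Cldn5 and Kdr (camera adjusted p = 5.78e-08, and adjusted p = 0.0452 with an estimated correlation). Neutrophil markers had a median of -1.35, with 5 of 13 genes that fell adjusted over the list alone (camera adjusted p = 2.65e-06, and adjusted p = 0.0519 with an estimated correlation). None of the genes of either list passed over all genes tested. Astrocyte, mural, monocyte and homeostatic microglia lists were lower, and lysosome, oxidative phosphorylation and oligodendrocyte lists higher, with the preset correlation. The camera adjusted p was 0.00299, 0.0373, 0.0329, 0.0476, 0.00993, 0.0248 and 0.0476 in that order, and all 7 calls were lost with an estimated correlation, with an adjusted p between 0.138 and 0.449. The other 18 lists did not pass.

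The number of calls depended on single libraries and on how the spread was estimated (edgeR). Of these 10 genes, Gm10800 alone passed without either WT library, Cst7, Gm10800 and Gm10801 passed without either cKO library, and Cst7 and Gm10800 passed without either WT/AD library. In contrast, 678 genes rose and 626 fell without cKO/AD replicate 1, 605 and 597 without cKO/AD replicate 2, and 738 and 632 with the 4 libraries of WT and WT/AD alone. With GC content corrected, Apoe had a log2 fold change of 1.32 (edgeR adjusted p = 0.122), and the other 9 genes kept direction and threshold.

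The comparison of cKO with WT asked what Calhm2 deletion changes without AD. No single gene passed the threshold, 0 higher and 0 lower by edgeR, while 1596 genes had an unadjusted p under 0.05, where 1104 would be expected by chance. DESeq2 called 127 higher and 158 lower, limma-voom 0 and 3, and edgeR on the 4 libraries alone 24 and 98. Without cKO/AD replicate 1 edgeR called 303 higher and 375 lower, and without cKO/AD replicate 2 it called 238 and 392. The 10 genes with the smallest raw p were Gm10800, Cavin1, Cldn5, Gm42031, Pcp4l1, Gm10801, Acta2, Ltbp4, Crip2 and Myl9, all with negative fold changes. Cavin1, a caveolar coat protein gene, was at 1015 ± 123 CPM in WT and 190.1 ± 2.8 CPM in cKO (log2 fold change -2.42, adjusted p = 0.0548). Cldn5, a tight junction gene of brain endothelium, was at 230.4 ± 0.208 and 55.2 ± 4.03 CPM (-2.06, adjusted p = 0.0548), and Acta2, the smooth muscle actin gene, at 109.5 ± 5.28 and 35.8 ± 6.15 CPM (-1.61, adjusted p = 0.2). Gm42031, a predicted gene, had 584 counts in WT and 0 in cKO, at least 204-fold lower against a floor of 3 counts over the group (adjusted p = 0.126).

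As lists, markers of vessels, astrocytes and neutrophils were lower in cKO than in WT. Endothelial markers had a median log2 fold change of -1.44, negative in 16 of 16 genes, with 11 that fell adjusted over the list alone and 0 over all genes tested (camera adjusted p = 1.32e-13). Mural and fibroblast markers had a median of -0.96 over 12 genes, astrocyte markers -0.69 over 15 and neutrophil markers -0.999 over 13 (camera adjusted p = 1.19e-06, 3.7e-06 and 2.28e-06; 5, 8 and 4 genes fell adjusted over the list alone). These 4 lists held with an estimated correlation, with an adjusted p between 0.0307 and 0.0423. Neuron markers had a median of 0.01 (adjusted p = 0.981) and oligodendrocyte markers 0.30 (adjusted p = 0.0626).

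By camera with the preset correlation, 12 further lists were lower in cKO. All but the immediate-early, glycolysis and cell cycle lists also passed fry (adjusted p between 0.00848 and 0.0464). Type I interferon response genes had a median of -0.90 over 25 genes (camera adjusted p = 2.54e-07), of which 3 fell adjusted over the list alone; Ifit3 was at 24.3 ± 0.59 CPM in WT and 10.4 ± 1.68 CPM in cKO (adjusted p = 0.511). Homeostatic microglia genes had a median of -0.51 (21 of 22 negative, camera adjusted p = 5.36e-06), with P2ry12 at 5842 ± 547 CPM and Tmem119 at 5607 ± 727 CPM in cKO (adjusted p = 0.629 and 0.782). Lysosomal genes had a median of -0.42 (32 of 32 negative, camera adjusted p = 4.26e-06). The others were complement and phagocytic receptors, immediate-early genes, antigen presentation, cytokines and chemokines, glycolysis, calcium handling, cell cycle, choroid plexus markers and DAM genes (camera adjusted p between 5.57e-05 and 0.0321). None of the 12 held with an estimated correlation (adjusted p between 0.0919 and 0.479), and 0 genes of any list passed over all genes tested.

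**Figure D2:**
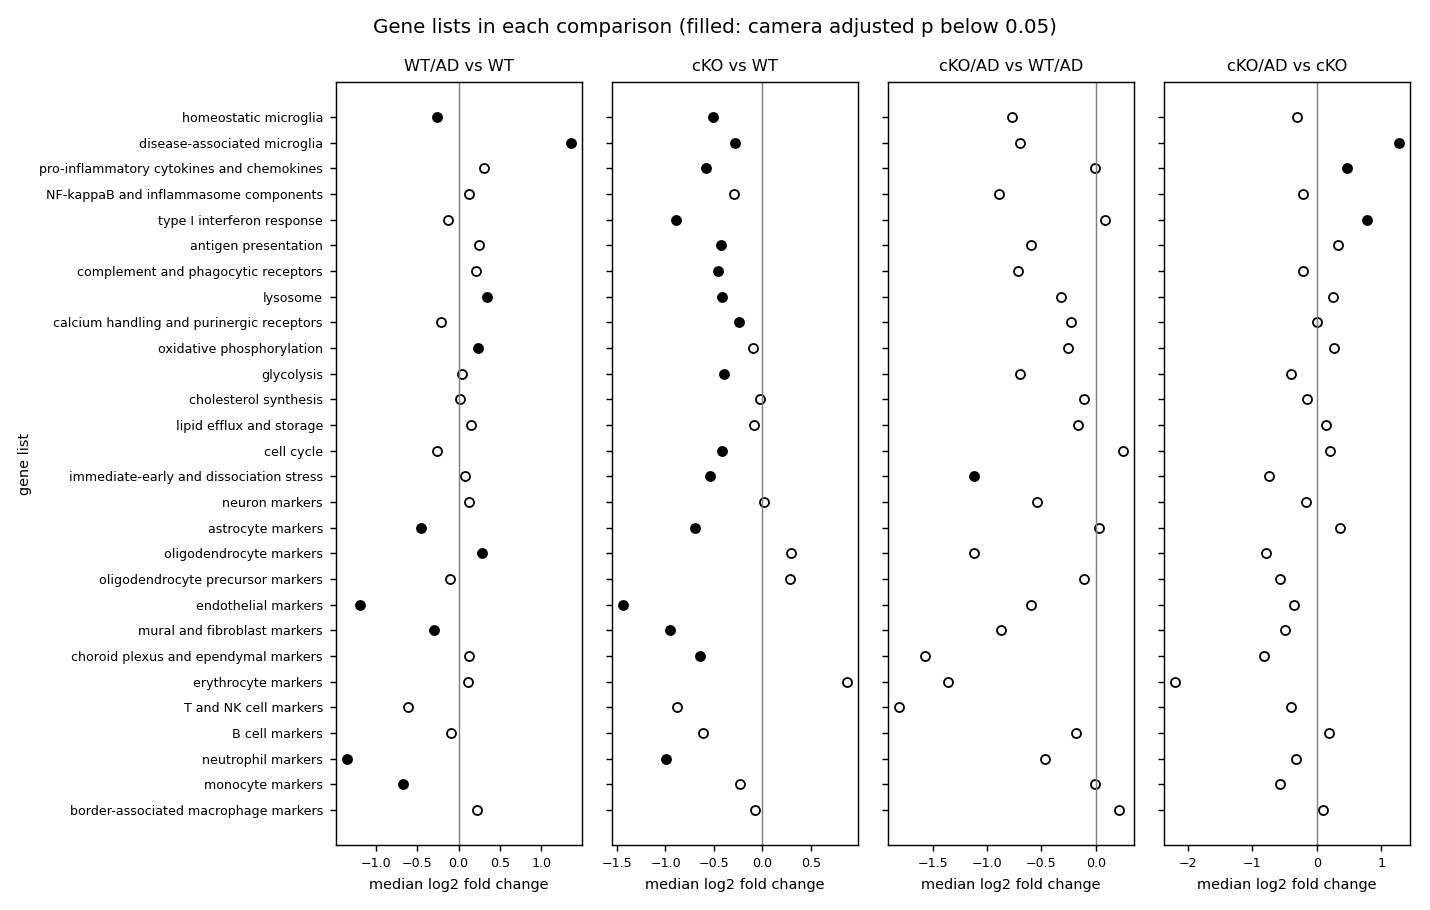
Median log2 fold change (x axes, scaled per panel) of the tested members of each of 28 fixed gene lists (y axis) in 4 comparisons; filled circles passed camera with the preset correlation. The DAM list is at 1.36 in WT/AD against WT and 1.28 in cKO/AD against cKO, and the endothelial list at -1.44 in cKO against WT.

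The comparison of cKO/AD with WT/AD, the groups named in the series title, asked what Calhm2 deletion changes in AD mice. Several DAM genes that were high in WT/AD were lower in cKO/AD. Trem2 (ENSMUSG00000023992.14), a lipid-sensing receptor of microglia, fell from 242.7 ± 4.69 to 56.7 ± 10.6 CPM (log2 fold change -2.10, SE 0.236, edgeR adjusted p = 0.00635). The lysosomal protease genes Ctsd and Ctsl fell from 456.3 ± 115 to 118.4 ± 16.5 CPM and from 1108 ± 1.09 to 395.3 ± 28.7 CPM (-1.95 and -1.49, both adjusted p = 0.00642). Lgals3, which encodes galectin 3, fell from 46.8 ± 0.878 to 10.6 ± 6.64 CPM, and Cst7 from 532.1 ± 25.9 to 239.9 ± 54.3 CPM (-1.15, adjusted p = 0.0463). Of the 26 DAM genes 10 fell and 1, Spp1, rose (240.2 ± 30.9 to 394.3 ± 27.8 CPM); adjusted over the list alone 12 fell and 1 rose. Clec7a was at 88.8 ± 5.89 and 96.9 ± 17.3 CPM in WT/AD and cKO/AD (adjusted p = 0.742), and Itgax at 28.4 ± 5.6 and 14.01 ± 2.46 CPM (adjusted p = 0.123). The list as a set had a median log2 fold change of -0.70 and did not pass camera (adjusted p = 0.172). By fry it was lower (adjusted p = 0.000885), 1 of 14 lists of microglial and other genes that were lower by that test. With GC content corrected, 3 of the 11 calls were kept, those of Trem2, Ctsd and Ctsl (-0.76, -0.88 and -2.07; adjusted p = 0.0427, 0.0344 and 0.0149). The other 8 were not, among them Lgals3 (-1.32, adjusted p = 0.066), Cst7 (-1.09, adjusted p = 0.0905), Spp1 (0.05, adjusted p = 0.884) and Apoe, which went from -0.71 to 0.999 (adjusted p = 0.0334). Of the 11 calls edgeR kept 0 without WT/AD replicate 1, 3 without WT/AD replicate 2 (Trem2, Ctsd and Ctsl), 5 without either WT library, 6 without either cKO library, 11 without either cKO/AD library and 0 with the 4 libraries of these groups alone; DESeq2 and limma-voom kept 11. The first cKO/AD library, which had the fewest genes with a count, also had the highest share of mitochondrially encoded counts, 4.73% against 1.37% to 2.37% in the other 7, so the level of every gene group in cKO/AD includes a library that stands apart on these measures.

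Some members of other microglial gene lists were lower in cKO/AD. These lists were homeostatic, complement and phagocytic receptor, lysosomal and antigen presentation genes. None of the 4 lists passed camera as a set (adjusted p = 0.227, 0.13, 0.179 and 0.288 in that order). All 4 were lower by fry (adjusted p = 0.0247, 0.0066, 0.0108 and 0.0156 in the same order). Of 22 homeostatic microglia genes 7 fell and 1 rose; Csf1r, the receptor that microglia need for survival, fell from 6123 ± 105 to 1824 ± 656 CPM and Adgrg1 from 445.3 ± 6.62 to 81.5 ± 54.7 CPM. Tmem119 fell from 7699 ± 359 to 2533 ± 1650 CPM, but its log2 fold change went from -1.60 to -0.11 with GC content corrected (adjusted p = 0.839). P2ry12 was at 5263 ± 1110 and 7317 ± 119 CPM (adjusted p = 0.157). Complement and phagocytic receptor genes fell in 7 of 25 and rose in none, lysosomal genes fell in 8 of 32, and antigen presentation genes fell in 7 of 19 and rose in 1. H2-Aa, an MHC class II gene, fell from 283.8 ± 20.1 to 122.7 ± 25.9 CPM (-1.21, and -1.04 with GC content corrected). C1qa fell from 10840 ± 2000 to 3431 ± 1590 CPM and was at -0.03 with GC content corrected (adjusted p = 0.945).

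Inflammatory and interferon genes went both ways. In the NF-kappaB and inflammasome list Rela, a subunit of NF-kappaB, fell from 63.2 ± 3.36 to 5.41 ± 4.84 CPM, and Pycard, the inflammasome adaptor, rose from 42.95 ± 2.92 to 118.1 ± 4.97 CPM; 4 of 20 fell and 1 rose. In the interferon list 3 of 25 rose and 1 fell; the viral RNA sensor gene Ifih1 rose from 21.3 ± 2.5 to 63.6 ± 24.7 CPM and Ifit1 from 10.1 ± 1.01 to 25.8 ± 2.19 CPM, and both lost the call with GC content corrected (adjusted p = 0.13 and 0.221). Ifit3 was at 12.7 ± 2.63 and 23.3 ± 2.11 CPM (adjusted p = 0.1). No member of the cytokine and chemokine list passed. Il1b was at 1.96 ± 0.977 and 0.584 ± 0.184 CPM, Tnf at 5.51 ± 0.463 and 2.97 ± 4.2 CPM and Nlrp3 at 6.51 ± 1.19 and 2.65 ± 3.26 CPM (adjusted p = 0.368, 0.721 and 0.428). Immediate-early and dissociation stress genes fell in 10 of 26 and rose in 1, among them Jun (109.5 ± 14.4 to 32.5 ± 9.64 CPM) and Klf2 (33.8 ± 8.61 to 2.2 ± 1.5 CPM). This was the only list to pass camera here (median -1.12, adjusted p = 0.00601, and adjusted p = 0.684 with an estimated correlation), and it had an adjusted p of 0.443 with GC content corrected.

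Among calcium handling and purinergic receptor genes 7 of 36 rose and 5 fell. The calcium-permeable channel gene Trpm7 rose from 79.8 ± 8.35 to 236.8 ± 40.6 CPM, Atp2b1, a plasma membrane calcium pump gene, rose from 633.8 ± 20.1 to 1495 ± 409 CPM, and the calmodulin gene Calm3 fell from 138.1 ± 24.8 to 34.3 ± 1.61 CPM. Glycolysis genes fell in 6 of 20 and rose in 1, with Gapdh at 568.2 ± 101 and 143.5 ± 45.2 CPM and Hk2 at 31.04 ± 0.565 and 87.5 ± 31.1 CPM. Oxidative phosphorylation genes fell in 7 of 37 and rose in 1, cholesterol synthesis genes fell in 4 of 23 and rose in 3, lipid efflux and storage genes rose in 3 of 21 and fell in 1, and cell cycle genes rose in 1 of 29 and fell in 1. With GC content corrected, the falls of P2ry6, Aldoa, Cox6a1 and Tm7sf2 turned to 0.161, 0.0024, 0.283 and 0.098, and none passed. Of all 3980 calls in this comparison 1030 kept direction and threshold with that correction. Calls in this and the neighbouring paragraphs without a corrected value may therefore not hold.

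Some markers of other cell types passed the threshold, while none of their lists passed camera (adjusted p between 0.19 and 0.932). Oligodendrocyte markers split, with 7 of 15 that fell and 3 that rose; Mag fell from 475.2 ± 33.3 to 149.1 ± 24.6 CPM. Neuron markers fell in 6 of 20 and rose in 1, with Slc17a7 at 86.5 ± 19.1 and 9.38 ± 2.51 CPM. Endothelial markers fell in 5 of 16, mural and fibroblast markers in 3 of 12, neutrophil markers in 2 of 13, and choroid plexus and astrocyte markers in 1 each. With GC content corrected, Cldn5, among the endothelial falls, and Clu, the astrocyte fall, turned sign and lost the call. Their log2 fold changes were then 0.729 and 0.296 (edgeR adjusted p = 0.0789 and 0.343). The smooth muscle gene Acta2 fell from 71.8 ± 8 to 20.97 ± 1.26 CPM. One monocyte marker, Ms4a4c, rose, and no member of the oligodendrocyte precursor, erythrocyte, T and NK cell, B cell or border-associated macrophage lists passed.

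In all, 1728 genes rose and 2252 fell (edgeR). The largest rises were those of Pappa2, Scgn, Rps6ka6, Sp8, Zim1, Dchs2, Hells, Stil, Ska3 and Glp1r. Sp8, a transcription factor gene, rose from 3.27 ± 1.48 to 56.9 ± 19 CPM (log2 fold change 4.12, adjusted p = 0.00641), and Scgn, which encodes a calcium-binding protein, from 0.377 ± 0.0271 to 9.31 ± 2.25 CPM. Pappa2 had 1 count in WT/AD and 205 in cKO/AD, a ratio of 258 (95% interval 45.8 to 10200). The largest falls were in genes with almost no counts in cKO/AD. Vwa7, Fam222a, Lrrc29, Col17a1, Slc52a3, Lrrn4cl and Skor1 had 0 counts there and were at least 147-, 109-, 90.5-, 88.7-, 76.7-, 74.6- and 68.3-fold lower against the floor of 3 counts over the group. Hps6, Egr4 and Ngfr had 1 count each in cKO/AD against 1005, 951 and 522 in WT/AD, ratios of 798 (143 to 31500), 755 (135 to 29900) and 414 (74.1 to 16400).

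These counts moved with transcript GC content and with single libraries. The log2 fold change fell from a median of 0.78 in the lowest GC decile to -1.76 in the highest (Spearman's rho -0.46 across genes, which are not independent replicates). With GC content corrected 737 genes were higher and 614 lower. Of the 3980 calls, 1030 kept direction and threshold and 374 turned sign. The 4 libraries of these groups alone gave 0 higher and 0 lower by edgeR, where the fit of all libraries had 7438 genes at an unadjusted p under 0.05, DESeq2 called 2919 and 3517, and leaving out WT/AD replicate 1 left 2 of the calls and WT/AD replicate 2 left 1103.

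**Figure D3:**
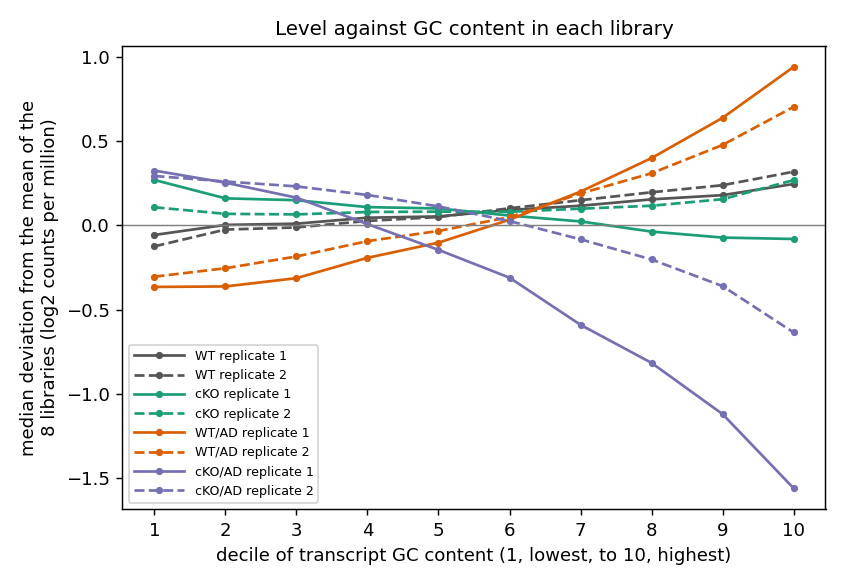
Median deviation from the mean of the 8 libraries (y axis, log2 CPM) over tested genes in each decile of transcript GC content (x axis) in each library (lines; dashed for replicate 2). In the highest decile the cKO/AD libraries are at -1.56 and -0.64 and the WT/AD libraries at 0.94 and 0.70.

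The comparison of cKO/AD with cKO asked what changes in AD mice when Calhm2 is deleted. DAM genes were again higher. Cst7 rose from 8.21 ± 4.16 to 239.9 ± 54.3 CPM (log2 fold change 4.87, SE 0.383, edgeR adjusted p = 0.0137), Clec7a from 11.4 ± 1.1 to 96.9 ± 17.3 CPM, Spp1 from 55.5 ± 4.43 to 394.3 ± 27.8 CPM and Lpl from 16.7 ± 1.1 to 99.4 ± 4.47 CPM. Ctse rose from 2.44 ± 0.9 to 41.05 ± 3.7 CPM, Ccl3 from 9.11 ± 2.39 to 91.5 ± 32 CPM, Ccl6 from 200.2 ± 9.32 to 824.6 ± 307 CPM, and Apoe from 974.2 ± 40.1 to 2495 ± 185 CPM (adjusted p = 0.0489). The DAM list had a median of 1.28, with 6 of 26 genes that rose over all genes tested and 17 adjusted over the list alone (camera adjusted p = 4.19e-09, and adjusted p = 0.0563 with an estimated correlation). Trem2 was at 75.2 ± 17.9 and 56.7 ± 10.6 CPM (adjusted p = 0.316).

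The interferon list was higher as well (median 0.78, camera adjusted p = 3.34e-05), with 6 of 25 genes that rose adjusted over the list alone, as was the cytokine and chemokine list (median 0.46, camera adjusted p = 0.0221, and adjusted p = 0.0745 with GC content corrected), of which 1 of 18 genes rose over all genes tested. Neither held with an estimated correlation (adjusted p = 0.339 for both), and the other 25 lists did not pass. In all, 14 genes rose and 34 fell (edgeR), 48 calls, where 5 simulations with no difference and each group's own spread gave between 5 and 34 calls. Among the falls, Hps6 had 471 counts in cKO and 1 in cKO/AD (ratio 439, 95% interval 78.4 to 17400) and Klf11 had 544 and 3 (ratio 169, 57.5 to 822). The lipid transporter gene Mfsd2a fell from 19.3 ± 5.22 to 0.835 ± 0.459 CPM, and the neuronal genes Grin2c and Slc17a7 fell from 46.7 ± 15.9 to 5.45 ± 0.396 CPM and from 71.03 ± 17.3 to 9.38 ± 2.51 CPM. Of the 48 calls none was left without either WT library, without cKO replicate 2 or with the 4 libraries of the 2 groups alone (edgeR; 5168 genes at an unadjusted p under 0.05 with all libraries), and 2 were left without either WT/AD library. Without cKO replicate 1 20 were left, whereas 611 genes rose and 1401 fell without cKO/AD replicate 1, and 3017 and 5553 without cKO/AD replicate 2.

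The effect of AD was compared between mice with and without Calhm2, in libraries that do not overlap. Of the 7 genes higher in WT/AD than in WT, 6 were also higher in cKO/AD than in cKO: Apoe, Ccl3, Clec7a, Cst7, Ctse and Lpl. Of independent lists 0.00444 would be expected (Fisher's exact test, p = 1.3e-19). That p treats genes and lists as independent, which they are not. Both comparisons take the spread of a gene from the same fit of all libraries, and Apoe, Clec7a, Cst7 and Lpl are all DAM genes. The 3 genes lower in WT/AD had no overlap with the 34 lower in cKO/AD. Across all 22089 genes, which are not independent replicates, the fold changes of the 2 comparisons correlated at r = -0.0721 (Spearman's rho -0.154). The deletion effects with and without AD correlated at r = 0.00572 (rho 0.142). The AD effect and the deletion effect in AD, which share the WT/AD libraries, correlated at r = -0.342, against -0.493 in simulations without any effect; the covariance was -1.28 against a simulated -0.919 (-0.982 to -0.882), a difference of -0.361. The simulations gave every group the pooled spread of each gene (common dispersion 0.362). The own-group dispersion was 0.155 in WT/AD and 1.08 in cKO/AD, so the simulated values are no sound benchmark. They cannot tell how much of the correlation the shared libraries give. Part of the correlation may come from the shared libraries, which were not split because each comparison would keep 1 of them.

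The interaction tested whether the effect of Calhm2 deletion differed between AD and non-AD mice. Of all genes, 2 were higher and 4 lower (edgeR), where 5 simulations with no difference and each group's own spread gave between 0 and 4 calls. Slc25a22, a mitochondrial glutamate carrier gene, was at 103.3 ± 1.07 CPM in WT, 103.6 ± 24.5 CPM in cKO, 240.5 ± 30.5 CPM in WT/AD and 16.7 ± 4.06 CPM in cKO/AD (log2 difference -3.85, adjusted p = 0.0331). Grin2c, a glutamate receptor subunit gene, had a difference of -4.47 and Hps6 of -8.78 (both adjusted p = 0.0371). The other 3 were the predicted genes Gm10800, Gm10801 and Gm21887. For the DAM genes the difference did not pass over all genes tested. It was -1.67 for Trem2 (adjusted p = 0.0589), -2.32 for Cst7 (adjusted p = 0.0642) and -0.53 for Apoe (adjusted p = 0.293). Adjusted over the list alone, 4 of 26 were lower and 1 higher. The DAM list did not pass camera (adjusted p = 0.551) and was lower by fry (adjusted p = 0.018). The interferon, astrocyte and endothelial lists had higher differences (medians 0.95, 0.81 and 0.89; camera adjusted p = 0.00269, 0.0216 and 0.0216), none of which held with an estimated correlation (adjusted p = 0.392 for each). Without either WT library, either WT/AD library or cKO replicate 2, Gm10800 alone was left of the 6; without cKO/AD replicate 1 or 2, 1115 and 2717 genes were higher and 1956 and 5167 lower.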

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

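The tests of GC content, of other cell types and of blood cells, and the tests of cKO/AD replicate 1 over all genes and of a weight per group, were chosen after the results were seen; the simulation of unequal spread and the test of cKO/AD replicate 1 on the disease-associated list were written before their results.

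A difference between AD and non-AD mice in the effect of Calhm2 deletion was called for 6 genes by the edgeR interaction test; 5 simulations with no difference and each group's own spread gave between 0 and 4 calls. Of the 6, 5 passed in voom with a weight per group, which gave between 0 and 6 calls in the same simulations. Slc25a22 had a log2 difference of -3.85, Grin2c of -4.47, Hps6 of -8.78, Gm21887 of -3.58, Gm10800 of 12.6 and Gm10801 of 12.3; those of Hps6 and Gm10801 rest on groups with 1 count and depend on the prior count. Gm10800 was at 750.2 ± 136 CPM in WT, 42.02 ± 17.1 CPM in cKO, 0.436 ± 0.111 CPM in WT/AD and 152 ± 37.4 CPM in cKO/AD (n = 2). With GC content corrected, Slc25a22, Hps6, Gm10800 and Gm10801 kept the call, and Grin2c and Gm21887 lost it. As lists, the interferon response (camera adjusted p = 0.00269), astrocyte markers (0.0216) and endothelial markers (0.0216) differed in the same way, and none held with an estimated correlation.

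The first pattern weighed is the many genes past the threshold between cKO/AD and WT/AD. As the whole cause, a GC trend is argued against by the 1030 of 3980 calls that kept direction and threshold once it was removed. Unequal spread as the whole cause is argued against by the 2211 that kept them in voom with a weight per group. That fit gave at most 15 calls here in simulations with no difference. Whether cKO/AD replicate 1, with 4.73% mitochondrial counts and 18693 genes with a count, is the cause stays open. Without it all 3980 calls kept direction, and 3727 kept the threshold as well. That fit leaves 1 cKO/AD library, so the spread of this group does not enter and the 3727 cannot decide the question. What makes the libraries tilt with GC content stays open: replicate 1 minus replicate 2 tilted in cKO/AD (rho -0.171), cKO (-0.206) and WT/AD (0.166), less than cKO/AD against WT/AD (-0.46) but about as much as cKO against WT (-0.18), and with 2 libraries per group a bias of preparation and a difference between the groups cannot be told apart. For the calls not kept with group weights unequal spread stays open: the own-group dispersion was 1.08 in cKO/AD and 0.155 in WT/AD, the 4 libraries alone gave 0 calls, and edgeR gave at most 28 calls here in simulations with no difference, but up to 34 in cKO/AD against cKO, where 18 of the 48 calls kept direction and threshold with group weights. An effect of the deletion in AD mice remains possible and was not separated from these.

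The second pattern is the lower endothelial, mural, astrocyte and neutrophil markers in cKO than in WT. Fewer cells of every other type would lower all their markers, yet the oligodendrocyte median was 0.296 against an endothelial median of -1.44. The permutation p of 1e-05 over 100000 resamples, the smallest they can give, came from shuffling genes between the 2 lists. Genes are not independent replicates, so this p does not measure the spread between libraries. A GC trend is argued against, since 4 of the 4 lists passed camera after its correction. Fewer vessel fragments with their blood would lower erythrocyte markers too, yet their median was 0.877, positive in 5 of 5 genes (camera adjusted p = 0.0786). That met the prediction written against this cause (permutation p = 5e-05 against endothelial markers, with genes that are not independent replicates). A condition on the level, not part of that prediction, was applied as well. At mean levels of 0.92 to 4.89 CPM these 5 genes did not meet it, so the cause stays open. The same 4 lists were lower in WT/AD than in WT as well, where Calhm2 is intact (medians -1.19, -0.30, -0.45 and -1.35 in that order). By camera with an estimated correlation the endothelial list alone held there (adjusted p = 0.0452, 0.255, 0.138 and 0.0519 in the same order). A difference of the 2 WT libraries from the rest stays open beside an untested change in the vessel cells or in microglial isolation with the deletion.

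The third pattern is the set of 11 disease-associated genes past the threshold between cKO/AD and WT/AD. A GC trend as the whole cause is argued against for Trem2, Ctsd and Ctsl, the 3 that kept the call after its correction. With the replicate block added to the correction, Trem2 lost the call. A GC trend may account for part of the change of Trem2 (log2 fold change -2.10, then -0.76) and Ctsd (-1.95, then -0.88). Of the other 8, 4 (Apoe, Csf1, Timp2 and Spp1) shrank to under 50% of their log2 fold change or turned sign, Tyrobp and Lgals3 shrank less, and for these a GC trend and an effect of the deletion cannot be told apart. Gpnmb (-2.14, SE 0.616, then -2.19, SE 0.599) and Cst7 (-1.15, SE 0.326, then -1.09, SE 0.328) kept their fold and lost the call as the adjustment grew stricter with fewer genes past the threshold. All 11 kept direction without cKO/AD replicate 1 and without WT/AD replicate 1, though the calls were lost by edgeR without the latter. Each of these fits leaves 1 library in a group whose spread does not enter. Neither can decide whether 1 library is the cause. With the 4 libraries alone edgeR kept 0 of the 11 calls. With all libraries DESeq2 kept 11 and voom with a weight per group 9. An effect of the deletion in AD mice on these genes stays a hypothesis.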

How the results depend on the processing

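The GC offsets, GC offsets with replicate block, voom with group quality weights and camera after GC offsets were chosen after seeing the data; the other alternatives were planned. Pairs are genes higher and lower, and the cause was not tested except where fewer libraries or another spread enter by construction. A lone library in an arm was assumed to vary like the other groups.

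WT/AD against WT (7 and 3): DESeq2 275 and 256, limma-voom 12 and 9, no filter 149 and 129, only the 2 groups 738 and 632, quality weights 652 and 683, library size only 4 higher, replicate block 1 higher, GC offsets 7 lower, GC offsets with replicate block 6 lower. cKO against WT (0 and 0 by edgeR, 1596 at an unadjusted p under 0.05): DESeq2 127 and 158, limma-voom 3 lower, no filter 50 and 92, only the 2 groups 24 and 98, quality weights 148 and 296, DESeq2 size factors 2 lower, GC offsets 2 lower. cKO/AD against WT/AD (1728 and 2252): DESeq2 2919 and 3517, only the 2 groups 0 and 0 by edgeR, GC offsets 737 and 614, with replicate block 657 and 534, quality weights 1037 lower. cKO/AD against cKO (14 and 34): DESeq2 1436 and 1915, limma-voom 73 higher, no filter 1123 and 1934, stricter filter 96 and 218, only the 2 groups 0 and 0, replicate block 9 and 13, GC offsets 17 lower, with replicate block 10 lower, quality weights 137 and 10, library size only 18 and 139. Interaction (2 and 4): DESeq2 size factors 5 and 15, library size only 4 and 20, DESeq2 1226 and 1537, limma-voom 263 and 421, no filter 1070 and 1600, stricter filter 96 and 185, replicate block 1 and 0, GC offsets 6 higher, with replicate block 1 and 0, quality weights 563 and 340. Library size only shifted the median of all genes by 0.15 in cKO against WT, -0.22 in cKO/AD against cKO and -0.21 in the interaction. Same-number deviations correlated at -0.033 to 0.061 across genes, so no strong pairing by replicate number was seen, though 2 libraries per group cannot exclude one.

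Without 1 library, genes higher ranged from 0 to 678 and lower from 1 to 626 in WT/AD against WT, 0 to 303 and 0 to 392 in cKO against WT, 1 to 3906 and 1 to 6286 in cKO/AD against WT/AD, 0 to 3017 and 0 to 5553 in cKO/AD against cKO, and 1 to 2717 and 0 to 5167 in the interaction. Lists higher ranged from 1 to 4 and lower from 3 to 7, 0 to 2 and 10 to 17, 0 to 0 and 1 to 6, 2 to 4 and 0 to 1, and 1 to 4 and 0 to 0 in that order. The correlations of effects ranged from -0.0985 to -0.0131 (AD effects), -0.0542 to 0.0491 (deletion effects) and -0.419 to -0.281 (shared WT/AD).

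Lists with an estimated correlation: 1 higher and 1 lower in WT/AD against WT, 4 lower in cKO against WT, 0 lower in cKO/AD against WT/AD, 0 higher in cKO/AD against cKO and in the interaction. With fry, 1 list was higher and 13 lower in cKO against WT, and 14 were lower in cKO/AD against WT/AD. It gave 5 higher and 5 lower in cKO/AD against cKO, and 4 higher and 4 lower in the interaction. In cKO against WT, 1 was higher by library size only and 1 after GC offsets; after GC offsets 0 were lower in cKO/AD against WT/AD and 5 higher in cKO/AD against cKO. The AD effects correlated at -0.0853 (stricter filter), -0.0425 (GC offsets) and 0.529 over the 10 genes past the threshold in WT/AD against WT. The deletion effects correlated at 0.115 (stricter filter) and -0.0254 (GC offsets). The pair sharing WT/AD correlated at -0.313 (stricter filter), -0.31 (GC offsets) and -0.973 over those 10 genes. These were picked by their WT/AD levels, which enter both comparisons of that pair with opposite sign, so a negative value is built in.

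In cKO/AD against WT/AD 9 named genes reversed with GC offsets and with GC offsets plus replicate block: P2ry6 0.161 and 0.137, C1qc 0.00031 and 0.0013, Gaa 0.0093 and 0.0024, Cox6a1 0.283 and 0.253, Aldoa 0.0024 and 0.0025, Tm7sf2 0.098 and 0.098, Apoe 0.999 and 0.983, Clu 0.296 and 0.288, and Cldn5 0.729 and 0.715. Of the 11 disease-associated calls there, 3 were kept with GC offsets and 2, Ctsd and Ctsl, with the replicate block added. The Tnf interaction ranged from -8.99 (without cKO/AD replicate 2) to 1.01 without 1 library. Simulated 2-fold changes in WT/AD against WT were recovered at 4.55% by edgeR with the pooled spread, so most changes of that size would be missed.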

Other observations

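No test was added for this part after the results were seen; the values below are described without explanation.

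Some transcripts known to be abundant and short in microglia had low counts in these libraries, while C1qa and Apoe, given above, had high counts. No list of short transcripts was tested. Tyrobp was at 7.41 ± 1.27 CPM in WT and 20.4 ± 5.49 CPM in WT/AD, Cd52 at 8.06 ± 0.642 and 11.1 ± 2.38 CPM, and Cox7c at 2.73 ± 0.838 and 6.31 ± 1.25 CPM (n = 2). Ndufa1 stayed under 1 CPM in all 4 group means. Ribosomal protein genes took between 0.273% and 0.451% of the counts of a library.

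Xist was at most at a mean of 0.57 CPM in any group, and the Y-linked gene Ddx3y was at 157.2 ± 11.6 CPM in WT, 175.7 ± 9.82 CPM in cKO, 105.5 ± 4.3 CPM in WT/AD and 307.5 ± 92.6 CPM in cKO/AD. Ets1, a transcription factor gene, was at 303.9 ± 2.99 CPM in WT, 153.4 ± 1.69 CPM in cKO, 121.3 ± 25.2 CPM in WT/AD and 363.4 ± 23.1 CPM in cKO/AD. Atp2b3, a calcium pump gene, was at 53.6 ± 1.32, 80.8 ± 3.3, 104.5 ± 5.07 and 31.7 ± 2.25 CPM in the same order.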
